A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

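Total RNA was extracted from rainbow trout liver and sequenced as cDNA libraries, per the labels' protocols. The 3 control libraries (18 °C) and the 3 heat libraries (24 °C for 8 h) were grouped by the treatment given in the labels. The series title also names ribosome profiling, which was not analysed here. Bowtie2 2.2.8 and StringTie are named in the submitters' processing notes. The genome build, the annotation and the test behind the authors' p-values are not given in the sources used here, so no coordinates are printed.

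The deposited table gives, per gene and library, a read count and an FPKM value, and per gene the authors' mean FPKM, log2 fold change, p-value and adjusted p, per the file headers. The authors' log2 fold change equals log2 of the ratio of the mean FPKM values, with 0.001 in place of a mean of 0. All 5045 listed genes have an adjusted p of at most 0.049875 and an absolute log2 fold change of at least 1.00019 in the authors' deposited table. The table is fixed-width text with 8 characters per column, so gene identifiers, symbols and descriptions are truncated. Only 55 distinct identifiers remain, copies with the same symbol can be told apart only by their values, and 318 rows have a symbol of 8 characters that may be incomplete. Of the 4519 rows with a symbol, 1854 carry a symbol that also stands in the RefSeq gene table of assembly USDA_OmykA_1.1. The 822 lines of wrapped annotation text were left out.

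The planned edgeR quasi-likelihood and DESeq2 fits were not run, because the fixed-width layout kept the count columns from being machine-verified as counts. In their place limma-voom (limma 3.58.1, R 4.3.3), listed before the data were examined as another test to try, was used on the whole-number counts. Because the list was selected on the outcome, libraries were scaled by whole-library totals recovered from the ratio of count to FPKM, taken over genes with at least 200 counts and 5 FPKM. Relative to control replicate 1 these were 0.999 and 1.02 for control replicates 2 and 3, and 1.55, 1.17 and 1.14 for heat replicates 1 to 3. Genes with at least 10 counts in 3 libraries were tested, and p was adjusted by Benjamini-Hochberg over these 4766 listed genes alone. Fold changes in the text are those of limma-voom, with levels in FPKM. On simulated counts for the 4766 genes with 200 changed, limma-voom recovered 77% of 2-fold and 97% of 4-fold changes, and 5.9% of its calls were false. The simulation used a spread set by hand and left most genes unchanged, whereas every listed gene had been selected as changed. Its rates therefore do not carry over to the listed genes.

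The 30 gene groups were fixed before the data were examined. A gene belonged to a group by its symbol or description, and 18 entries of obviously wrong matches were removed by hand after directions had been seen, on the identity of the gene alone. The group test was Fisher's exact test, two-sided, of rises against falls in a group against the other tested genes, adjusted over the groups with at least 5 listed members. Adjusted over the list alone, all tested members of each group also passed. Camera was not used, since it needs genes that were not selected on the outcome. Tests of other groups and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

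Genes named in the text followed a rule fixed before the data were examined, except where the text says that a gene was named after its value was seen. Where a symbol has several copies, a value belongs to the copy that the rule took unless stated. The rule took the 10 largest rises and 10 largest falls with non-overlapping groups, a mean of at least 1 FPKM in the higher group and an informative name. It also took the 4 members with the smallest p in each group of at least 3, and the heat shock, cirbp and serpinh1 families. The rule allowed an informative description in place of a symbol, but the truncated descriptions were not used, and clone names were left out. Some genes that the rule takes are not reported here. Where a group had no counts, a fold was computed against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% interval. The alternatives were other scalings, count filters, pseudocounts on FPKM, a replicate block, leaving out each library, and other group memberships. TMM and median-of-ratios scaling were computed by code written for this work.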

Results

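RNA-seq libraries from the liver of rainbow trout (Oncorhynchus mykiss) were compared between a control group held at 18 °C and a heat stress group held at 24 °C for 8 h, with 3 libraries in each group. The question, from the design text, was how liver mRNA levels differ under heat stress. The deposited table lists 5045 genes, and each of them has an adjusted p under 0.05 and an absolute log2 fold change over 1 in the authors' deposited table. The listed genes were therefore selected on the outcome, and nothing can be said here about genes outside the list. Read counts over the listed genes summed to 1409460, 1410753 and 1421082 in control replicates 1 to 3. In heat replicates 1 to 3 they summed to 3586127, 2764179 and 2663575. The whole-library depth is unknown, and only the ratios of the library totals were recovered. At equal library totals, the listed genes took 1.66-fold more counts in the heat group than in the control group. The labels do not say that the libraries came from separate fish, so limma-voom p-values measure the spread between these libraries, which may be technical. Fisher's exact p-values of the gene groups count genes as independent units and measure no spread between libraries. Copies of one symbol often moved the same way, so these p-values may be too small. With 1 gene per symbol, 12 groups passed in place of 14.

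Among the listed genes, those of the cytosolic heat shock, endoplasmic reticulum and acute-phase groups rose in heat more often than the other listed genes. Those of the cell cycle, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and splicing groups fell more often, and members of each of these except the cell cycle group also rose. Among the genes taken by the naming rule, the largest rise was that of hspa1b, an inducible cytosolic heat shock protein of the 70 kDa class, from 0.093 ± 0.0321 to 347.4 ± 9.77 FPKM (SD, n = 3 per group). Among the 10 largest falls was that of leap-2b, an antimicrobial peptide gene, from 830.5 ± 22.6 to 44.4 ± 3.79 FPKM (SD, n = 3 per group). Of the 4766 genes with enough counts to test, 2770 rose and 1996 fell with limma-voom at a Benjamini-Hochberg adjusted p under 0.05, and 4707 of these changed at least 2-fold. All tested genes passed, as the selection of the list makes likely, so the count is no screen of the transcriptome. With median-of-ratios scaling over the listed genes, which assumes that most of them do not change, 1678 rose and 1996 fell, 2928 changed at least 2-fold, and the median log2 fold change of the tested genes moved by -0.91. With a pseudocount of 1 FPKM, 1859 changed at least 2-fold.

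In the authors' deposited table, 2880 listed genes had a positive and 2165 a negative log2 fold change. The direction in the authors' deposited table matched that of the limma-voom fit for all 4766 tested genes. Both rest on the same 6 libraries and library totals, so this match is no independent check. In the authors' deposited table, 4273 of the genes had an adjusted p under 0.01 and 1571 had an absolute log2 fold change of at least 2.

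The group of cytosolic heat shock genes held 64 tested members, of which 61 rose and 3 fell. Most encode chaperones or co-chaperones of the cytosol, but not all, since the product of SERPINH1 acts in the endoplasmic reticulum. An hsp90a.1 gene rose from 10.4 ± 0.828 to 850.5 ± 15.8 FPKM (SD, n = 3), a log2 fold change of 6.36 ± 0.07 (SE). A second hsp90a.1 gene rose from 4.86 ± 0.527 to 435.0 ± 4.82 FPKM. An Hspa4 gene rose 46.9-fold, and the procollagen chaperone gene SERPINH1 rose 26.7-fold. The list did not take in the co-chaperone gene dnaja, which rose 142-fold, or the procollagen chaperone under the symbol hsp47, which rose 30.3-fold to 1512 ± 59.0 FPKM. Genes named hsp70 rose between 42.5-fold and 133-fold, but reads of near-identical copies could be split between them, so the value of each copy is uncertain. One of these copies rose 71.7-fold, or 36.1-fold without control replicate 2. The same holds for hsp30, of which several listed copies carry identical values. The copy of hsp30 with the largest change rose from 0.173 ± 0.299 to 125.3 ± 4.77 FPKM, and its 6 control counts all lay in control replicate 1, without which it was at least 1048-fold higher in heat against a floor of 3 counts over the group. Members among the 10 largest rises with no control counts were HSPA4L, at least 65.7-fold higher in heat, and unc45b, a myosin chaperone, at least 82.9-fold higher, each against a floor of 3 counts over the group. The members that fell, named after their values were seen, were a copy of PTGES3, hsbp1b and a copy of HSPA4, with log2 fold changes of -1.28, -2.49 and -1.62. The other listed copies of PTGES3 rose 4.20-fold and 7.65-fold, and those of HSPA4 also rose. Rises were more frequent in this group than among the other listed genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.08e-10).

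Genes of the endoplasmic reticulum and its unfolded protein response rose almost throughout, with 69 of 70 tested members higher in heat (Fisher's exact test, adjusted p = 1.84e-14). The luminal chaperone hspa5 rose from 77.3 ± 3.21 to 1691 ± 33.9 FPKM (SD, n = 3), a log2 fold change of 4.45 ± 0.04 (SE). The chaperone hyou1 rose 28.2-fold, the co-chaperone dnajc3a 29.2-fold and the disulfide isomerase PDIA6 10.3-fold. The exception, named after its value was seen, was a copy of ERN1, with a log2 fold change of -1.29, while its other 2 copies rose. Of the mitochondrial chaperones, 4 rose and 1 fell (adjusted p = 0.636 by Fisher's exact test). HSPD1 rose from 23.1 ± 0.693 to 254.7 ± 11.1 FPKM and hspe1 rose 2.84-fold, whereas Trap1 fell from 4.06 ± 0.76 to 0.729 ± 0.369 FPKM, a 6.62-fold fall that was 4.25-fold without heat replicate 1. In the group of proteasome and ubiquitin genes, 8 rose and 6 fell (Fisher's exact adjusted p of 1). The autophagy receptor gene Sqstm1 rose 7.15-fold and the segregase gene VCP 4.14-fold, and the most abundant copy of the polyubiquitin gene UBB fell 2.91-fold, while another copy rose.

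**Figure D1:**
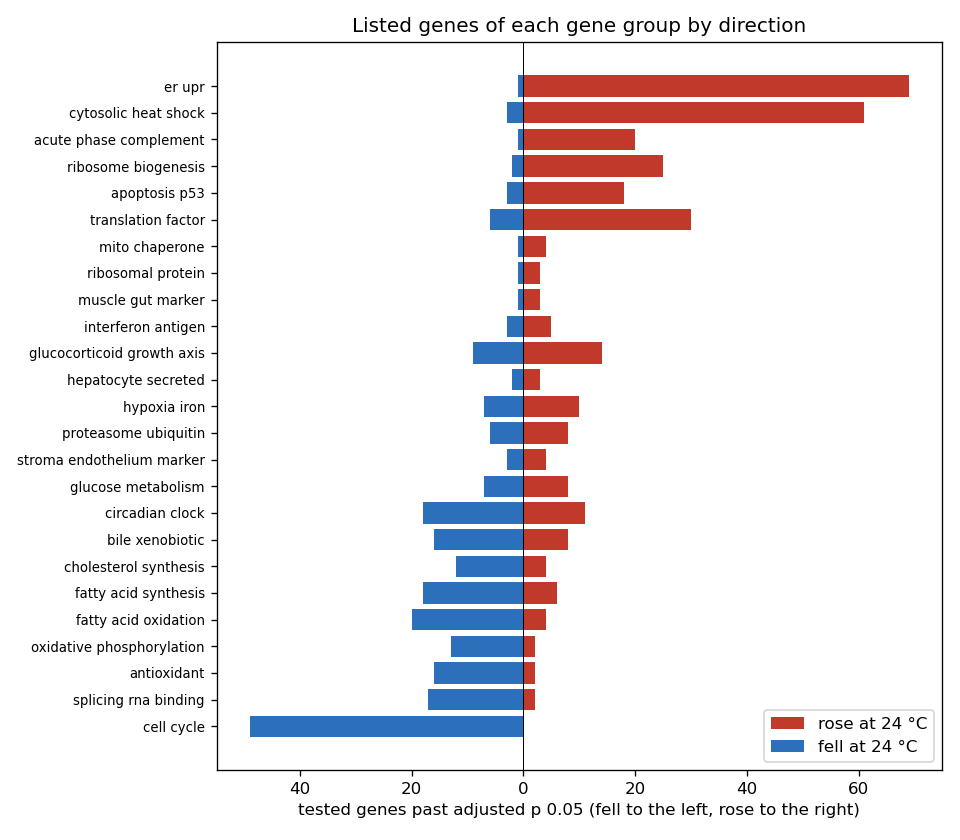
Numbers of tested listed genes that rose (right, red) and fell (left, blue) at 24 °C in each gene group with at least 5 listed members, at a limma-voom adjusted p under 0.05. The endoplasmic reticulum group stands at 69 rises and 1 fall, and the cell cycle group at 0 rises and 49 falls.

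All 49 tested cell cycle genes fell (Fisher's exact test, adjusted p = 5.32e-18). In the authors' annotation, the cell cycle pathway, tested after the data were seen, held 1 rise and 29 falls (Fisher's exact adjusted p = 7.56e-09). CDKN1B genes, which encode cell cycle inhibitors, were counted in the apoptosis and p53 group instead. Named after their values were seen, cdkn1ba, cdkn1bb and a copy of CDKN1B rose, with log2 fold changes of 1.55, 1.08 and 1.61. Another copy of CDKN1B, too low to test, was lower in heat. The nucleotide-synthesis gene rrm2 fell 4.20-fold, tk1 3.42-fold, the mitotic kinase gene cdk1 3.56-fold and the replication clamp gene pcna 2.60-fold. Of the splicing and RNA-binding genes, 17 fell and 2 rose (Fisher's exact test, adjusted p = 0.000142). SRSF2 fell 4.72-fold and SRSF3 fell 3.60-fold. Of the cold-inducible RNA-binding protein genes, cirbp-b fell 2.75-fold, CIRBP 3.02-fold and cirbpb 2.35-fold. The members that rose, named after their values were seen, were hnrnph3 and a copy of SRSF7, whose log2 fold changes were 1.74 and 1.86, while the other copy of SRSF7 fell 2.39-fold.

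Ribosome biogenesis genes rose in 25 of 27 tested members (Fisher's exact test, adjusted p = 0.000406). The helicase gene ddx27 rose 10.1-fold and wdr43 rose 3.28-fold. Of the translation factors and tRNA synthetases, 30 rose and 6 fell (Fisher's exact test, adjusted p = 0.0043), among them eif4g1a, up 6.67-fold, and the seryl-tRNA synthetase gene sars1, up 5.48-fold. Only 4 ribosomal protein genes were tested, of which 3 rose and 1 fell (Fisher's exact adjusted p = 0.895). Among them rps27 fell from 105.9 ± 8.83 to 49.2 ± 0.832 FPKM.

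Of the fatty acid synthesis genes, 18 fell and 6 rose (Fisher's exact test, adjusted p = 0.0034). FASN, the fatty acid synthase, fell from 85.4 ± 4.65 to 15.04 ± 0.51 FPKM in the more abundant copy, and the desaturase gene scdb fell from 1263 ± 13.9 to 386.4 ± 23.1 FPKM. Among the members that rose, named after their values were seen, were the 3 copies of the triglyceride-synthesis gene DGAT1 and 2 copies of the lipid droplet gene PLIN2, whose other copy fell 4.91-fold. Of the cholesterol synthesis genes, 12 fell and 4 rose (Fisher's exact test, adjusted p = 0.0201). SQLE fell 11.2-fold in the copy with the smaller p and 2.53-fold in its more abundant copy, and lss fell 5.97-fold. Among the members that rose, named after their values were seen, were srebf2, insig1 and ggps1, which encode regulators of sterol synthesis and a prenyl synthase. Of the fatty acid oxidation genes, 20 fell and 4 rose (Fisher's exact test, adjusted p = 0.000195). Pdk2 fell 4.02-fold and LPL 5.56-fold, and angptl4, which encodes an inhibitor of lipoprotein lipase, rose 6.19-fold. The group was therefore not limited to enzymes of oxidation. Other members, named after their values were seen, also went both ways. Hadha and the copies of HADH fell, with log2 fold changes of -1.09, -1.32 and -1.35. CPT1A rose at a low level, from 0.305 to 0.697 FPKM, with a log2 fold change of 1.18. The whole class of lipid metabolism in the authors' annotation, tested after the data were seen, held 49 rises and 53 falls and did not pass (Fisher's exact test, adjusted p = 0.246 over 82 classes). Of the oxidative phosphorylation genes, 13 fell and 2 rose (Fisher's exact test, adjusted p = 0.0021). ATP5MC3 fell 2.09-fold, and both members that rose were copies of the assembly factor gene Ndufaf4, named after their values were seen. Of the antioxidant genes, 16 fell and 2 rose (Fisher's exact test, adjusted p = 0.000204). GSTP1 fell 2.31-fold and gstr 2.13-fold, and the members that rose, named after their values were seen, were sesn2 and keap1b.

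Glucose genes went both ways, with 8 rises and 7 falls (Fisher's exact adjusted p of 1). The gluconeogenic gene pck1 rose from 9.09 ± 0.446 to 105.2 ± 2.75 FPKM and G6PC rose 5.09-fold, and the glycolytic genes tpi1b and PGAM1 fell 2.26-fold and 2.14-fold. Other members tied to glycolysis, named after their values were seen, rose. Among them were ENO1, up 3.22-fold, Pfkfb4, up 5.88-fold, and both copies of pfkfb3, up 92.6-fold and 25.8-fold. The copy of pfkfb3 that rose 25.8-fold rose 40.2-fold without control replicate 1, with 4 control counts left. In the glucocorticoid and growth group, 14 rose and 9 fell (Fisher's exact adjusted p of 1). The growth factor gene igf1 fell 3.39-fold and 3.93-fold in its 2 copies, and the glucocorticoid-responsive genes went both ways, with FKBP5 up 3.79-fold, Tat down 2.11-fold and Tsc22d3, named after its value was seen, down 6.94-fold. Clock genes fell in 18 and rose in 11 of 29 tested members (Fisher's exact test, adjusted p = 0.0606). Among them bhlhe40 fell 15.1-fold and a copy of Ciart rose 12.2-fold, while its other copy fell 6.52-fold. Of the bile and xenobiotic genes, 16 fell and 8 rose (Fisher's exact test, adjusted p = 0.0367), and the call ended with median-of-ratios scaling, at an adjusted p of 0.0873, and with 1 gene per symbol, at 0.229. CYP2B4 fell 4.49-fold and cyp1a1 3.20-fold, and Ugt2a2 rose 2.85-fold.

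**Figure D2:**
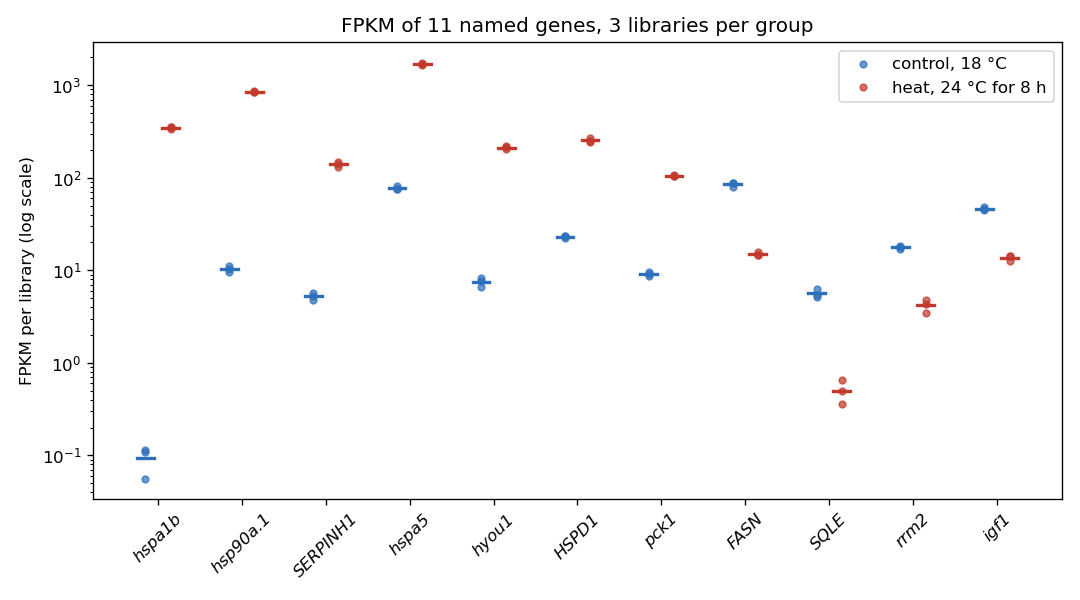
FPKM in each library, on a log axis, of 11 named genes in the control group (blue) and the heat group (red), with 3 libraries per group as points and the group mean as a bar. The most abundant of the copies taken by the naming rule is drawn, which for SQLE leaves out a more abundant copy that changed less, and hspa5 stands at a mean of 77.3 FPKM in control and 1691 FPKM in heat.

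Acute-phase and complement genes rose in 20 of 21 tested members (Fisher's exact test, adjusted p = 0.000692). The haemoglobin scavenger gene HP rose from 2298 ± 69.6 to 6491 ± 102.6 FPKM in its more abundant copy, and a complement c3 gene rose 5.11-fold. The member that fell, named after its value was seen, was leap2, with a log2 fold change of -1.11. The list did not take in leap-2b. Of the apoptosis and p53 genes, 18 rose and 3 fell (Fisher's exact test, adjusted p = 0.0246). The group mixed genes that promote and genes that restrain cell death, so its count gives no direction for apoptosis. GADD45B rose 6.71-fold and the survival gene BCL2L1 5.04-fold. The call of the group by Fisher's exact test ended when the genes removed by hand were put back, at an adjusted p of 0.106. It also ended with median-of-ratios scaling, at 0.0518, and with 1 gene per symbol, at 0.059. In the interferon and antigen group, 5 rose and 3 fell (Fisher's exact adjusted p of 1), with GBP1 up 7.16-fold. In the hypoxia and iron group, 10 rose and 7 fell (Fisher's exact adjusted p of 1), with ndrg1a down 10.9-fold and BNIP3 up 4.29-fold.

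Marker genes of other cell types were few among the listed genes. All 4 tested myeloid genes rose, among them mmp9, from 0.378 ± 0.0878 to 1.79 ± 0.14 FPKM, and Cd163, from 0.32 ± 0.156 to 6.53 ± 0.975 FPKM. Cd163 had only 4 counts over the control libraries and 101 over the heat libraries. The group was too small for the adjusted test, and 58.1% of the other tested genes also rose (Fisher's exact test, two-sided, unadjusted p = 0.145). No erythrocyte marker was among the listed genes. A single pancreas marker was tested, ins, whose counts rose from 1 to 62 over the group, a ratio of 48.5 (95% exact interval 8.39 to 1946), and a single lymphocyte marker was tested, IL7R, named after its value was seen, with a log2 fold change of 1.61. Stroma and endothelium markers rose in 4 and fell in 3 cases (Fisher's exact adjusted p of 1), with col1a1b down 2.48-fold. That group also held krt18, an epithelial keratin gene rather than a stroma marker, up from 87.8 ± 3.90 to 176.5 ± 3.61 FPKM. The krt18 call ended with median-of-ratios scaling. The 4 tested members of the muscle and gut group were the gut genes fabp2, CDX1, anpepa and vil1, with no muscle marker among them. Of these, 3 rose and 1 fell (Fisher's exact adjusted p of 0.895), with fabp2 down 3.09-fold. Of the genes secreted by hepatocytes, 3 rose and 2 fell (Fisher's exact adjusted p of 1). An APOB gene rose 326-fold to 26.3 ± 0.547 FPKM, and rbp4 fell from 5950 ± 207.4 to 1998 ± 135.8 FPKM. In the group of oestrogen-responsive and egg-coat genes, 3 rose and 1 fell, with zp2.3 up 2.91-fold.

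Outside these groups, VWA7 had no control counts and was at least 140.8-fold higher in heat, against the same floor. Further genes among the 10 largest rises were tcbp2, from 0.0973 ± 0.114 to 31.9 ± 0.697 FPKM, a 343-fold rise that was 205-fold without control replicate 3 and rested on 1 control count without control replicate 2, a ratio of 950.6 (95% exact interval 170.4 to 37570), and lrp1ba, with 1 count in control and 963 in heat, a ratio of 753 (95% exact interval 135 to 29780). Further genes among the 10 largest falls were a copy of MFAP4, which fell 19.3-fold, Cplx1, which fell 20.04-fold, a copy of CABLES1, which fell 19.8-fold, a copy of PRC1, which fell 17.9-fold, and a copy of Cd276, which fell 16.7-fold. Other listed copies moved the opposite way for CABLES1, up 2.49-fold, for Cd276, up 4.12-fold, and for MFAP4, whose other 4 copies rose, the most abundant of them from 30.6 to 225.6 FPKM. The copies of CABLES1, Cplx1, PRC1 and Cd276 that fell most had only 6 to 13 counts over the heat libraries, and single libraries moved their folds. Without heat replicate 1, Cplx1 fell 12.7-fold and CABLES1 had 2 heat counts, a ratio of 59.2 (95% exact interval 16.1 to 493). Without heat replicate 2, PRC1 fell 8.63-fold and Cd276 9.08-fold, and without heat replicate 3 PRC1 fell 30.6-fold. The clock-interacting gene CIPC had 289 counts in control and 1 in heat, a ratio of 369.5 (95% exact interval 65.8 to 14640), and the troponin gene Tnni1 had 205 and 1, a ratio of 262 (95% exact interval 46.5 to 10400). The single heat count of each lay in heat replicate 2, without which CIPC was at least 85.7-fold and Tnni1 at least 60.8-fold lower against the floor. These intervals and the floor cover counting error only.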

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

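The quasi-Poisson test, the filter of 50 counts, identical genes kept once, 1 gene per symbol and the groups without removal by hand were chosen after seeing the data. The number of genes past the threshold was 4766 and stayed within 1.5 times under every alternative, and leaving out each library gave 4754 to 4763. Median-of-ratios scaling gave 1678 rises and 2928 genes changed at least 2-fold, since it takes the median listed gene as unchanged. The pseudocount of 1 FPKM gave 1859 genes changed at least 2-fold, since it shrinks the folds of low genes. The filter of 50 counts gave 1201 falls from the 3272 genes it left. An absolute log2 fold change of at least 2 was held by 1571 genes in the authors' deposited table, since it is a stricter threshold. TMM over the listed genes gave 4533 genes and moved the median log2 fold change by -0.55. Of the 146 named genes, 9 lost their call under median-of-ratios scaling and 1 under TMM, and none changed sign under the alternatives that tested it. Both scalings moved the fold changes downward, by -0.91 and -0.55 at the median, so they could not weaken a fall. The number of falls stayed at 1996 under both, and no scaling that moves the fold changes upward was tried. Listed genes had been selected at an absolute log2 fold change over 1, so a change of sign was unlikely from the start. The number of groups past the threshold was 14, with a range of 12 to 14. Groups that were not past the threshold changed the sign of their difference in percent of rises from the other genes, and the cause was not tested. For proteasome and ubiquitin genes it was 1.18 under TMM, 4.34 under median-of-ratios scaling and 0.0568 without a filter. For glucose genes it was 4.34 under median-of-ratios scaling. With 50 counts it was -7.08 for the glucocorticoid and growth group, -6.18 for hypoxia and iron, -3.3 for hepatocyte genes and -13.3 for muscle and gut. With 1 gene per symbol it was -4.39 for hypoxia and iron and -7.71 for hepatocyte genes. For stroma it was 0.0567 without a filter and 8.56 without removal by hand. A replicate block gave 4766 genes, 4700 of them changed at least 2-fold, and it changed no call. Same-numbered libraries had correlations of 0.036, 0.019 and -0.017 of their deviations. Control replicates 1 and 2 correlated best with the heat replicate of the same number, and control replicate 3 with heat replicate 2, at 0.024. All these correlations were small, so they cannot tell whether the numbers pair the libraries. The planned edgeR, DESeq2 and camera fits and the planned CPM filter were not run. Whole-library depth is unknown, so levels near a few counts limit the folds of low genes.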

Other observations

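The tests of gene classes, of scaling, of the label entries, of the splits and of random pairs were chosen after the result was seen, and hamp1 was named after its value was seen. Zinc finger genes of the C2H2 family, by the authors' annotation, rose in 155 and fell in 18 of 173 tested genes, against 150 and 99 of the other annotated transcription factors (Fisher's exact test, adjusted over 82 classes, p = 1.12e-10). HMG-box factors went the other way, with 5 rises and 14 falls (Fisher's exact adjusted p = 0.000198). Genes whose first pathway is N-glycan biosynthesis rose in 13 of 13 cases (Fisher's exact adjusted p = 0.00435).

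Genes of the Fanconi anaemia pathway, a DNA crosslink repair pathway, fell in 15 of 17 cases (Fisher's exact adjusted p = 0.00149), and peroxisome genes fell in 14 of 16 (Fisher's exact adjusted p = 0.00276). Hepcidin, hamp1, the peptide hormone of iron balance, rose from 1.22 ± 0.563 to 102.2 ± 2.49 FPKM (SD, n = 3).

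The count of 4766 genes came from the real grouping, and the highest count of the other splits of the 6 libraries was 1. With 3 libraries against 3 there are 10 splits, of which 1 gave as many genes, which is too few for a share under 0.05, and the genes had been selected on the real grouping.

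Replicates lay close together. At over 1000 mean counts, the median CV beyond counting error was 3.17% in 77 genes with an absolute log2 fold change over 3 and 2.33% in 88 genes between 1 and 1.2. If the authors' selection by adjusted p were the cause, strongly changed genes could show a wider spread. The ratio was 1.36 with a 95% bootstrap interval of 0.743 to 2.46, which leaves this open. Whether the libraries are technical or pooled repeats cannot be told apart from separate fish, since 0 label entries name a pool, an individual or the kind of replicate. No biological explanation was tested.

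Clock genes went both ways, with 11 rises and 18 falls, and as a group did not pass (Fisher's exact adjusted p = 0.0606). Scaling of the libraries would move all members by one shift. At least 16 of the 29 members lay over 3 standard errors from any one shift, so no single shift would leave all of them unchanged. However, every listed gene was selected at an absolute log2 fold change over 1, which alone sets rises and falls apart. Listed groups with both directions would tend to give this outcome, so it is no independent test of scaling. With median-of-ratios scaling 8 rises and 18 falls passed, so the calls of the other 3 that rose depended on the scaling. A difference in sampling time or feeding between the groups may also give such a pattern and cannot be told apart from heat, since 0 label entries give a time of day or feeding.

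Copies of a symbol moved together. Among 515 symbols with 2 tested genes, 455 pairs (88.3%) moved the same way, against 52.5% in permuted pairs (one-sided permutation p = 0.0001, the smallest 10000 permutations can give). Reads shared between copies may contribute, since 20.9% of these pairs differed by over 3 standard errors, against 31.1% of random pairs moving together (95% range 26.4% to 35.7%), but separate copies under shared regulation would give this too. Of the pairs that moved apart, 1 of 23 with KO annotation carried different KO identifiers, against 0 of 180 that moved together (Fisher's exact p = 0.113), so whether a symbol was given to different genes cannot be told apart from true divergence.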
